A study of Mus musculus with 2 samples.

How the data were processed

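Visium spatial gene expression libraries were analysed from 1 transverse heart section of a PD1 Het mouse and 1 of a PD1 KO mouse. Both animals had myocardial infarction surgery at postnatal day 2 and were collected 7 days later. For each section the deposited matrix holds raw UMI counts per gene and spot, made with Space Ranger 1.1.0 per the file headers. The submitters' processing notes name the genome builds mm10 and GRCm38. Aligner settings and the annotation release are not given in the sources used here. The matrices hold fewer spot barcodes than a capture area, by a rule that is not given either. Spot positions were not used here. Gene symbols were taken from the deposited feature tables, and 32235 of 32285 gene IDs were found in GENCODE vM21 (GRCm38), which gave chromosomes and positions.

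Spots with fewer than 500 UMIs were left out, and UMIs of the remaining spots were summed per section and scaled to CPM on all gene UMIs of the section. The PD1 Het section kept 12814494 UMIs and the PD1 KO section 23520499. With these totals, 3 counts, the limit that a count of 0 allows at 95% confidence, correspond to 0.234 and 0.128 CPM, and the same limit of 3 counts is given for shares of 0 spots. Intervals are 95% exact Poisson intervals for sums, exact binomial (Clopper-Pearson) intervals for shares above 0, and exact conditional intervals for ratios of sums. Each group has 1 section, so no test, p-value, standard error or count of changed genes was computed, and spots were not treated as replicates.

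The ratio of each gene is PD1 KO over PD1 Het. The median gene was taken over the 11455 genes with at least 100 UMIs in both sections together, and its log2 CPM ratio was subtracted where a ratio is called relative. A total of 35 gene lists, with 379 genes, were fixed before the data were examined, and 1 list gene, Mx1, was not matched to a symbol. The lists were ventricular cardiomyocyte markers, atrial markers, fetal and stress cardiomyocyte genes, fatty acid oxidation genes, glycolysis genes, fibroblast markers, scar matrix and activated fibroblast genes, endothelial markers, endocardial markers, smooth muscle markers, pericyte markers, epicardial markers, macrophage markers, resident and reparative macrophage genes, monocyte and injury macrophage genes, neutrophil markers, T cell markers, cytotoxic and NK cell markers, B cell markers, mast cell markers, PD-1 pathway and regulatory immune genes, MHC class II genes, MHC class I genes, interferon gamma response genes, type I interferon response genes, inflammatory cytokines and chemokines, complement genes, cell cycle genes, hypoxia genes, immediate early and heat shock genes, red blood cell genes, adipocyte markers, Schwann cell and nerve markers, lung epithelial markers and sex-linked genes. A list's median was taken over members with at least 10 UMIs in both sections together, and its interval from 500 Poisson draws. The median was placed among 10000 random lists of the same size matched on mean CPM in 20 bins. The percentile describes these libraries and is not a test. Members at least 1.5-fold above or below the median gene were counted.

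The named genes follow a rule fixed before the data were examined. Pdcd1, Cd274 and Pdcd1lg2 were always named. The 15 genes with the largest and the 15 with the smallest ratio were taken among genes with at least 100 UMIs in both sections together, without sex-linked, red blood cell, mitochondrial and ribosomal protein genes and unnamed gene models. In each list, up to 4 members with at least 30 UMIs were taken, the 2 with the most UMIs and the 2 with the largest absolute log2 ratio. Other members are named with the counts of a list and were chosen after their values were seen.

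Shares of spots with at least 1 UMI were computed after thinning each spot to 10000 UMIs, the largest of 5 preset depths that keeps at least 90% of the spots of each section, and also without thinning. Spots of each section were ranked by the share of their UMIs from the scar matrix list and divided into 5 bins of equal size. Spots of both sections were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 on 2000 variable genes, 20 principal components and 15 neighbours at resolution 0.5, without genes of the immune, sex-linked and red blood cell lists and without mitochondrial and ribosomal protein genes. No correction between sections was applied. A region was called matrix-rich when its matrix share was at least 1.5 times that of all spots. For each of the 11447 genes with an annotated transcript among the 11455, the share of 31-mers of the last 400 bases of its transcripts that also occur in any transcript of another gene was computed, and an end was called shared at 50%. For 9 genes all 31-mers of their transcripts were searched as well. Both searches were chosen after the ratios were seen.

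Alternatives were edgeR 4.0.16 TMM factors, median-of-ratios size factors computed here, a CPM total without mitochondrial genes, red blood cell genes and the 20 most abundant other genes, the mean of spot CPM, no spot filter or at least 2000 UMIs per spot, members with at least 1 or at least 50 UMIs, matrix-rich regions only or left out, other thinning depths, 10 bins, a ranking by fibroblast markers, resolutions 0.3 and 1, genes centred within each section, clustering with immune genes, and a minimum of 300 UMIs for named genes. The TMM scaling of Cd274, the ratios without the spot with the most UMIs, the stress list without Nppa and the 2 matrix-rich regions taken apart were added after the data were seen. Computing used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.

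The comparison of the PD1 KO section over the PD1 Het section was tested on simulated data, in which 200 of 11455 genes were changed. The median recovered log2 ratio was 0.59 for 1.5-fold higher genes, 0.96 for 2-fold and 2.01 for 4-fold, and -0.56, -0.98 and -2.00 for genes lower by the same folds. The interval held the true value for 97.1%, 100% and 91.2% of the higher genes, for 91.2%, 97.1% and 100% of the lower genes, and for 95.4% of the 11255 unchanged genes. Of 100 unchanged lists, 96 had a percentile in the middle 95%, and 100% of 20 lists made 1.5-fold higher lay above the 97.5 percentile. These 20 lists were all drawn from the same 34 genes. Both simulated sections were independent Poisson draws from 1 common rate per gene, with no trend with abundance and no genes that vary together. The simulation therefore checks the computation and does not show that intervals or percentiles are calibrated for these data. For the search of shared ends, 20 of 20 simulated ends came out within 1 percentage point of the copied share.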

Results

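Gene expression was measured across heart sections with Visium, an assay that captures RNA on an array of barcoded spots, each of which covers several cells. The mice were C57BL/6 animals with myocardial infarction surgery at postnatal day 2, and hearts were frozen 7 days after it. There was 1 section from a PD1 Het heart and 1 from a PD1 KO heart. The PD1 Het section held 812 spots, of which 811 had at least 500 UMIs, with 12814494 UMIs in total and a median of 15475 UMIs and 3694 genes per spot. In the PD1 KO section 851 of 859 spots were kept, with 23520499 UMIs and a median of 27134 UMIs and 5679 genes per spot. Mitochondrial genes took 25.6% of the UMIs in the PD1 Het section and 15.9% in the PD1 KO section. Sex-linked transcripts also differed: Xist, the RNA that coats the inactive X chromosome, had 541 UMIs in the PD1 Het section and 1 in the PD1 KO section, while the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 1 and 2900 UMIs together.

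The comparison asks how transcripts of the infarcted neonatal heart differ when PD-1, an inhibitory receptor of activated T cells, is lost. No replicates exist and no replicate check was possible, so values describe these 2 libraries, no test was run, and all intervals cover counting error only. The gene lists, the rule for named genes, the scaling, the spot filter and the ranking of spots were fixed before the data were examined. Relative to the total UMIs, the median gene lay at a log2 ratio of 0.33, or 1.26-fold, in the PD1 KO section, and the 13 mitochondrial genes at a median of -0.73. Log2 ratios below are PD1 KO over PD1 Het relative to this median gene unless they are called CPM ratios, and both are given for a list where their signs differ. The median CPM ratio of matched random lists was lower for lists of abundant genes. It was 0.15 for ventricular cardiomyocyte markers, 0.18 for fatty acid oxidation genes and 0.20 for fibroblast markers, against 0.38 for MHC class II genes. Lists of abundant genes thus tend to lie below the median gene, while the percentile compares a list with genes of like abundance.

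Pdcd1, the targeted gene, which encodes PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, GRCm38), had 0 UMIs in both sections. This allows up to 0.234 CPM in the PD1 Het section and 0.128 CPM in the PD1 KO section, so a difference was not detectable at this depth, and the zero counts say nothing about the genotype labels. Cd274, which encodes the ligand PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), was higher in the PD1 KO section, with 50 UMIs in 48 spots against 4 UMIs in 4 spots, or 2.13 against 0.312 CPM. Its relative log2 ratio was 2.44 (0.99 to 4.37). Pdcd1lg2, which encodes the other ligand PD-L2, had 1 UMI in the PD1 Het section and 2 in the PD1 KO section, too few for a ratio. The list of PD-1 pathway and regulatory immune genes had a median of 0.10 (-0.22 to 0.44), at percentile 68.0 of the random lists, with 2 of 8 members at least 1.5-fold above the median gene and 1 at least 1.5-fold below it. Among them Ptpn11, the phosphatase SHP-2 that acts downstream of PD-1, lay at 0.24 (0.10 to 0.39), and Tgfb1 at -0.21 (-0.38 to -0.04), although its CPM was slightly higher in the PD1 KO section (35.4 against 32.5).

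Genes of antigen presentation were higher in the PD1 KO section. The MHC class II genes, which present peptides to CD4 T cells, had a median of 1.03 (0.83 to 1.26), above all of the 10000 random lists (percentile 100), and 4 of 7 members lay at least 1.5-fold above the median gene and 0 as far below it. Together they made up 36.4 CPM in the PD1 Het section and 98.8 CPM in the PD1 KO section. H2-Aa lay at 1.40 (1.0 to 1.8), H2-Eb1 at 1.35 (0.95 to 1.77), H2-Ab1 at 1.24 (0.91 to 1.59) and Cd74, the invariant chain, at 1.03 (0.81 to 1.26). Ciita, the transactivator of the class II genes, had only 5 and 8 UMIs. MHC class I genes had a median of 0.32 (0.13 to 0.48) at percentile 99.45, with 3 of 10 members above and 0 below. H2-K1 lay at 0.74 (0.63 to 0.85) and B2m, the light chain of class I molecules, at 0.62 (0.55 to 0.70).

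Interferon gamma response genes, which T and NK cells induce in their neighbours, had a median of 0.30 (0.13 to 0.44) at percentile 97.4, with 3 of 14 members above and 2 below. Iigp1 and Irgm2, interferon-inducible GTPases, lay at 0.77 (0.41 to 1.16) and 0.74 (0.36 to 1.14), and Irf1 at -0.11 (-0.39 to 0.17), against 0.22 by CPM. The type I interferon response genes did not share this position. Their median was -0.26 (-0.37 to -0.08) at percentile 1.06, with 0 of 14 members above and 2 below, although their CPM median was 0.08. Oas1a, an antiviral RNA sensor, lay at -2.15 (-3.24 to -1.13) and Rtp4 at 0.35 (-0.04 to 0.75). Inflammatory cytokines and chemokines had a median of 0.27 (0.05 to 0.65) at percentile 90.2, with 3 of 12 members above and 0 below. Ccl8 lay at 1.72 (0.76 to 2.84), but 8 of its 10 PD1 Het UMIs were in 1 spot, and without the spot with the most UMIs in each section its CPM ratio was 18.0-fold in place of 4.14-fold. Tnfsf10 lay at 0.52 (0.17 to 0.88) and Cxcl12 at 0.09 (-0.03 to 0.21). Complement genes had a median of -0.01 (-0.35 to 0.21) at percentile 50.1, against a CPM median of 0.32, with 0 of 8 members above and 3 below, and Serping1, an inhibitor of the pathway, at -0.72 (-0.83 to -0.60).

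Macrophage genes differed by list. The general macrophage markers had a median of 0.10 (-0.11 to 0.18) at percentile 85.3, with 2 of 14 members above and 0 below, namely Ctss, a lysosomal protease of antigen-presenting cells, at 1.60 (1.33 to 1.89) and Mpeg1 at 0.95 (0.63 to 1.29). Lyz2 lay at 0.36 (0.26 to 0.46), and C1qb at -0.12 (-0.24 to 0.01), although its CPM was higher in the PD1 KO section. Monocyte and injury macrophage genes had a median of 0.45 (0.07 to 0.62) at percentile 99.83, with 4 of 11 members above and 1 below. Arg1 lay at 2.62 (1.33 to 4.29) with 5 and 71 UMIs, of which 26 were in 1 spot, and Lgals3 at 1.58 (1.20 to 1.99). The sum of this list lay at -0.11 (-0.15 to -0.06), opposite in sign to its median and to its summed CPM ratio of 0.22, because it is dominated by Fabp5 and Cd63, both at -0.22 relative to the median gene and 0.11 by CPM. Resident and reparative macrophage genes had a median of -0.83 (-0.93 to -0.63), below all random lists (percentile 0), with 0 of 12 members above and 8 below. Lyve1, a hyaluronan receptor of resident macrophages and lymphatic vessels, lay at -1.54 (-2.12 to -0.96), Cd163 at -1.39 (-2.49 to -0.30), Stab1 at -0.65 (-0.77 to -0.52) and Gas6 at 0.24 (0.12 to 0.35). The sum of the resident list lay at -0.30 (-0.36 to -0.24), while its CPM ratio was 0.04.

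Lymphocyte transcripts were few. T cell markers had a median of 0.13 (-0.28 to 0.72) at percentile 65.8, with 3 of 12 members above and 1 below. Their sum, mostly Thy1, lay at -0.18 (-0.35 to -0.02), opposite in sign to the median and to the summed CPM ratio. Trac, the constant chain of the alpha T cell receptor, had 18 and 54 UMIs and lay at 0.38 (-0.42 to 1.23), so a difference was not detectable at this depth, and Trbc2, with 15 UMIs in each section, lay at -1.21 (-2.34 to -0.07). Cytotoxic and NK cell markers had 3 members with enough UMIs, a median of 0.25 (-1.21 to 2.79) at percentile 64.3, and 1 member above and 1 below. The member above was Ccl5, a chemokine of cytotoxic lymphocytes, and 155 of its 243 UMIs in the PD1 KO section were in 1 spot. The sum of the list, mostly Ccl5 in the PD1 KO section, had 24 and 277 UMIs and lay at 2.32 (1.72 to 2.99). After thinning to 10000 UMIs, a UMI of the list was present in 1.32% (0.634 to 2.41) of PD1 Het and 4.05% (2.82 to 5.62) of PD1 KO spots. At 5000 UMIs these shares were 1.01% (0.435 to 1.97) and 2.59% (1.63 to 3.90), with overlapping intervals. B cell markers were lower in the PD1 KO section relative to the median gene, with a median of -0.69 (-1.09 to -0.33) at percentile 0.13, 1 of 8 members above and 4 below. By CPM their median was -0.36 with an interval that reached 0 (-0.76 to 0.003). Their summed CPM ratio was -0.41 (-0.61 to -0.20), on 334 and 462 UMIs. Ms4a1, which encodes CD20, lay at -1.65 (-2.76 to -0.58) and Igkc at -1.26 (-1.75 to -0.79). Mast cell markers were lower too, at -1.05 (-1.20 to -0.64) and percentile 0, with 0 of 5 members above and 4 below, and Tpsb2 and Cma1, mast cell proteases, at -1.56 (-1.99 to -1.13) and -1.05 (-1.30 to -0.80). Of the 657 PD1 Het UMIs of this list, 346 were in 46 spots of 1 matrix-rich region, region 4 below. After thinning to 10000 UMIs, mast cell markers were present in 17.4% of PD1 Het and 18.1% of PD1 KO spots. At 5000 UMIs these shares were 12.2% and 11.0%. Neutrophil markers had a median of -0.27 (-0.93 to 0.38) at percentile 13.7, against 0.06 by CPM, with 0 of 5 members above and 2 below, and S100a8 and S100a9 at -0.84 (-1.31 to -0.36) and -0.81 (-1.26 to -0.35).

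**Figure D1:**
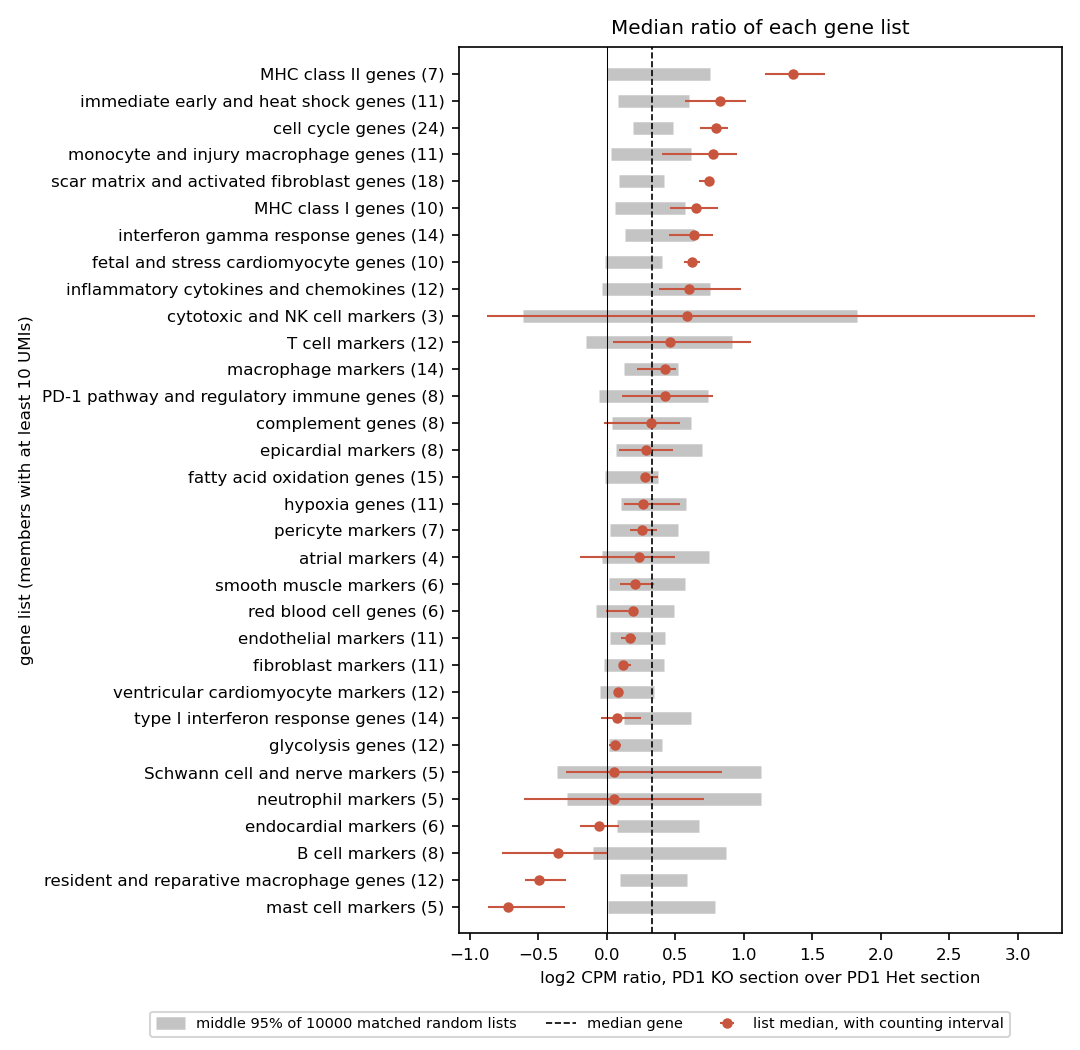
Median log2 CPM ratio of each gene list, PD1 KO section over PD1 Het section (points, with 95% counting intervals), the middle 95% of 10000 matched random lists (grey) and the median gene (dashed line, 0.33). MHC class II genes lie farthest to the right and mast cell markers farthest to the left; lists between 0 and the dashed line are higher by CPM and lower relative to the median gene, and lists with 1 member are not drawn.

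Cardiomyocyte stress genes were higher in the PD1 KO section, and ventricular cardiomyocyte markers lay below the median gene. Fetal and stress cardiomyocyte genes had a median of 0.29 (0.23 to 0.35) at percentile 99.99, with 3 of 10 members above and 0 below, and together made up 2510 CPM in the PD1 Het section and 4916 CPM in the PD1 KO section. Nppa, the natriuretic peptide that ventricles re-express under load, lay at 2.21 (2.16 to 2.25), with 358 and 2080 CPM, and Myh7, the slow myosin heavy chain, at 1.38, with 41.7 and 137 CPM. Des lay at -0.40 (-0.43 to -0.36). Without Nppa, a choice made after the values were seen, the median was 0.19 and the sum of the list 0.066 (0.046 to 0.087). Ventricular cardiomyocyte markers had a median of -0.24 (-0.25 to -0.24) at percentile 26.5, against 0.09 by CPM, with 0 of 12 members above and 1 below. Myl2 and Mb both lay at -0.57, and Ttn at 0.25 (0.22 to 0.29). Atrial markers had a median of -0.09 (-0.53 to 0.16) at percentile 30.2, against 0.24 by CPM, with 0 of 4 members above and 1, Stard10, below.

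The medians of the metabolic lists stayed near or below the median gene. Fatty acid oxidation genes had a median of -0.05 (-0.08 to 0.05) at percentile 82.3, against 0.28 by CPM, with 1 of 15 members above and 1 below. The member above was Pdk4, the kinase that turns glucose oxidation off, at 2.21 (2.07 to 2.35), with 36.5 and 213 CPM, and Acadm lay at 0.44 (0.39 to 0.48). Glycolysis genes had a median of -0.27 (-0.31 to -0.23) at percentile 6.15, against 0.06 by CPM, with 2 of 12 members above and 1 below. Hk2 lay at 0.62 (0.48 to 0.76), Slc2a1 at 0.61 (0.18 to 1.05), and Gapdh at -0.53 (-0.56 to -0.51). Hypoxia genes had a median of -0.07 (-0.21 to 0.20) at percentile 26.0, against 0.26 by CPM, with 1 of 11 members above and 0 below, and Vegfa at 0.29 (0.19 to 0.38). The sum of the hypoxia list lay at 0.16 (0.10 to 0.22), opposite in sign to its median.

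Cell cycle genes and immediate early genes were higher in the PD1 KO section. Cell cycle genes had a median of 0.47 (0.35 to 0.55), above all random lists (percentile 100), with 8 of 24 members above and 0 below, and 540 and 842 CPM in sum. Nusap1, a spindle protein, lay at 1.0 (0.63 to 1.40), Ccna2 at 0.95 (0.75 to 1.15), Pcna at 0.24 (0.13 to 0.35), and Ccnd1 at -0.29 (-0.41 to -0.18), although the CPM of Ccnd1 was slightly higher (72.4 against 70.5). Immediate early and heat shock genes, which stress and handling of tissue induce within minutes, had a median of 0.49 (0.24 to 0.69) at percentile 99.97, with 5 of 11 members above and 0 below. Fos lay at 2.09 (1.51 to 2.73), Egr1 at 1.55 (1.34 to 1.77), Dusp1 at 0.64 (0.51 to 0.77) and Jun at 0.59 (0.46 to 0.72).

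Scar matrix genes were higher in the PD1 KO section as a whole, and fibroblast markers lay below the median gene. Scar matrix and activated fibroblast genes had a median of 0.42 (0.34 to 0.43), above all random lists (percentile 100), with 5 of 18 members above and 0 below, and 6243 and 8920 CPM in sum. Thbs1, a matrix glycoprotein of wounds, lay at 1.22 (0.96 to 1.48) and Col8a1 at 1.11 (0.83 to 1.39), while Col3a1 lay at -0.04 and Sparc at -0.03, with higher CPM in the PD1 KO section for both. Fibroblast markers had a median of -0.21 (-0.24 to -0.16) at percentile 24.5, against 0.12 by CPM, with 0 of 11 members above and 0 below. Dcn lay at -0.23 (-0.27 to -0.18), against 0.11 by CPM, and Tcf21 at 0.37 (0.20 to 0.55).

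Of the vessel and lining cell lists, endocardial markers lay farthest from the median gene. Endothelial markers had a median of -0.16 (-0.23 to -0.12) at percentile 32.1, against 0.17 by CPM, with 0 of 11 members above and 0 below. Endocardial markers had a median of -0.39 (-0.52 to -0.24) at percentile 0.33, but -0.054 (-0.19 to 0.09) by CPM, and nearly equal sums of 88.1 and 89.3 CPM, with 0 of 6 members above and 2 below, and Cytl1 at -0.99 (-1.39 to -0.59). Smooth muscle markers had a median of -0.13 (-0.24 to 0.01) at percentile 28.8, against 0.20 by CPM, with 1 of 6 members above and 0 below. The member above was Cnn1, calponin, at 1.81 (1.34 to 2.32). Pericyte markers lay at -0.07 (-0.16 to 0.03) and percentile 47.2, against 0.26 by CPM and a sum at 0.07 (0.04 to 0.10), with 0 of 7 members above and 0 below. Epicardial markers lay at -0.04 (-0.24 to 0.16) and percentile 28.2, against 0.29 by CPM, with 1 of 8 members above, the keratin Krt8 at 1.20 (0.81 to 1.62), and 1 below. Red blood cell genes lay at -0.14 (-0.34 to -0.11) and percentile 46.8, against 0.19 by CPM, with 0 of 6 members beyond 1.5-fold either way. Schwann cell and nerve markers lay at -0.27 (-0.63 to 0.51) and percentile 20.5, against 0.06 by CPM, with 1 of 5 members above and 1 below. Adipocyte markers and lung epithelial markers had 1 member each with enough UMIs, Cidea at -0.38 (-0.53 to -0.23) and Ager at -0.48 (-1.14 to 0.20).

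After thinning of each spot to 10000 UMIs, MHC class II genes, Cd274 and Nppa were found in more spots of the PD1 KO section. Thinning was on all UMIs, of which mitochondrial genes took 25.6% in the PD1 Het and 15.9% in the PD1 KO section. Thinned PD1 KO spots thus tend to keep more UMIs of other genes, which can raise shares there. The Cd274 intervals below lie close together even without this. An MHC class II UMI was present in 22.4% (19.5 to 25.5) of 759 PD1 Het spots and 31.8% (28.7 to 35.1) of 839 PD1 KO spots, and an H2-Aa UMI in 3.16% (2.04 to 4.67) and 11.1% (9.04 to 13.4). Cd274 was present in 0.527% (0.144 to 1.34) and 2.26% (1.37 to 3.51), and Nppa in 62.3% (58.8 to 65.8) and 83.7% (81.0 to 86.1). Immediate early and heat shock genes were present in 82.6% (79.7 to 85.2) and 95.7% (94.1 to 97.0). T cell markers were present in 29.5% (26.3 to 32.9) and 31.3% (28.2 to 34.6). Thy1 gave 378 of the 453 PD1 Het and 717 of the 921 PD1 KO UMIs of this list, so these shares do not show how widespread T cell receptor transcripts were. Trac was present in only 7 of 759 PD1 Het spots and 21 of 839 PD1 KO spots, with overlapping intervals. Neutrophil markers were present in 7.38% (5.62 to 9.47) and 7.39% (5.71 to 9.37), and B cell markers in 19.6% (16.9 to 22.6) and 15% (12.7 to 17.6). At 5000 UMIs per spot these shares were 9.81% and 9.67% for B cell markers and 5.66% and 3.66% for neutrophil markers, so no order is read for these 2 lists. Pdcd1 was found in 0 spots of either section, which allows up to 0.395% and 0.358% by the limit of 3 counts used for zeros. Without thinning, the deeper PD1 KO section also had more spots with a B cell marker (33.0% against 26.5%), so no order is read from unthinned shares, which were 30% and 53.3% for MHC class II genes and 38.8% and 60.2% for T cell markers. Shares of single genes other than Pdcd1 and its ligands were chosen after the values were seen.

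Within each section, macrophage markers, MHC class II genes and fetal and stress cardiomyocyte genes were at higher levels in matrix-rich spots, with larger folds in the PD1 KO section. The ranking was made within each section, and the bins with the most matrix were not alike. Scar matrix genes had 14236 CPM in that of the PD1 Het section and 22909 CPM in that of the PD1 KO section. The folds below therefore compare spots of different matrix content. At matched matrix share, described below with its limits, macrophage markers were 0.991-fold by CPM, against 1.19-fold for the median gene, while MHC class II and stress genes were 1.87-fold and 1.48-fold. In the fifth of spots with the largest scar matrix share (162 PD1 Het and 170 PD1 KO spots), macrophage markers were 2.33-fold (2.19 to 2.47) the level of the other spots in the PD1 Het section and 3.88-fold (3.74 to 4.03) in the PD1 KO section. For MHC class II genes these folds were 2.33 (1.91 to 2.83) and 4.86 (4.48 to 5.28), for fetal and stress cardiomyocyte genes 1.5 (1.46 to 1.53) and 4.2 (4.15 to 4.25), and for Nppa 5.74 (5.41 to 6.09) and 13.8 (13.5 to 14.1). Without Nppa, chosen after the values were seen, the stress list had folds of 1.1 (1.07 to 1.14) and 1.67 (1.64 to 1.70). Not all lists were steeper in the PD1 KO section, with 1.97 and 1.98 for monocyte and injury macrophage genes, 1.98 and 1.74 for resident and reparative macrophage genes, 1.68 and 1.33 for type I interferon response genes, and 1.41 and 1.39 for immediate early and heat shock genes. Cell cycle genes were spread evenly, at 1.01 (0.948 to 1.07) and 1.02 (0.981 to 1.06). Mast cell markers, at 8.40 (7.14 to 9.89) and 4.14 (3.62 to 4.73), and endocardial markers, at 4.47 (3.97 to 5.03) and 2.63 (2.39 to 2.88), were less concentrated in the PD1 KO section. Between the sections, MHC class II genes were 3.65-fold (3.08 to 4.34) the median gene in the fifth with the most matrix and 1.61-fold (1.42 to 1.83) in the other spots. Macrophage markers were 1.59-fold (1.5 to 1.68) the median gene there and 0.879-fold (0.842 to 0.917) in the other spots, where their CPM was nonetheless higher in the PD1 KO section (338 against 301). Immediate early and heat shock genes were 1.60-fold (1.46 to 1.77) the median gene there and 1.5-fold (1.42 to 1.58) in the other spots.

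**Figure D2:**
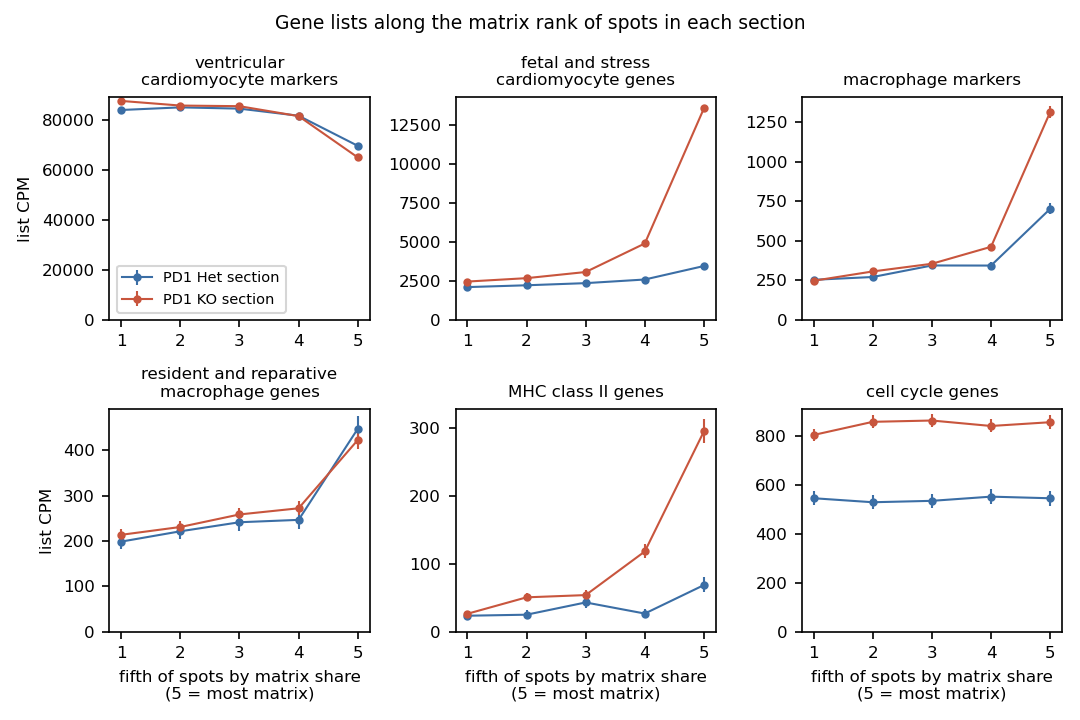
CPM of 6 gene lists in 5 bins of spots ranked by scar matrix share within each section, with 95% counting intervals; the horizontal axis runs from the least to the most matrix. MHC class II genes reach 295 CPM in the bin with the most matrix of the PD1 KO section and 68.6 CPM in that of the PD1 Het section, and cell cycle genes are flat in both sections.

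The matrix share of the spots themselves differed between the sections, with a median of 0.490% of UMIs in PD1 Het spots and 0.648% in PD1 KO spots. These are shares of all UMIs, a scale on which the median gene was itself 1.26-fold higher in the PD1 KO section. Much of the difference in matrix share can therefore reflect the scaling. For a comparison at matched matrix share, chosen after the values were seen, spots were divided into 10 bins with the same limits in both sections. Each bin was weighted by its PD1 Het UMIs. The bin with the least matrix held 148 PD1 Het and 19 PD1 KO spots and took 19.5% of the weight, the bin with the most 4.74%. Because the share is of all UMIs, lists that follow matrix can come out low. A low fold therefore does not show less of a list in like tissue. At matched share MHC class II genes were 1.87-fold (1.68 to 2.08) higher by CPM in the PD1 KO section, against 1.19-fold for the median gene, while macrophage markers were 0.991-fold (0.954 to 1.03), monocyte and injury macrophage genes 1.02-fold (0.988 to 1.06) and resident and reparative macrophage genes 0.914-fold (0.869 to 0.960). Stress cardiomyocyte genes were 1.48-fold (1.46 to 1.5) and cell cycle genes 1.51-fold (1.47 to 1.56) at matched share, and complement genes 0.874-fold (0.827 to 0.923).

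Clustering of spots gave 7 regions, of which region 4, led by Nppa and Col12a1, and region 6, led by Npr3 and Cytl1, were matrix-rich. Region 1, region 2, region 3 and region 5 each came almost wholly from 1 section, so they describe a library as much as a part of the tissue. Region 4 held 46 PD1 Het and 155 PD1 KO spots and region 6 held 51 and 39, so their pooled values compare different mixes. Stress genes were not left out of the clustering, and Nppa and Myh7 are among the leading genes of region 4. The values of the stress list by region can therefore reflect how spots were assigned. In the matrix-rich regions together, MHC class II genes lay at 1.66 (1.39 to 1.95) relative to the median gene of those spots, fetal and stress cardiomyocyte genes at 2.03 (1.98 to 2.07), macrophage markers at 0.40 (0.31 to 0.50), cell cycle genes at 0.47 (0.35 to 0.58), mast cell markers at -1.71 (-1.92 to -1.5) and red blood cell genes at -2.08 (-2.10 to -2.05). In the other regions the same lists lay at 0.39 (0.21 to 0.57), 0.01 (-0.01 to 0.03), -0.29 (-0.35 to -0.23), 0.32 (0.27 to 0.36), -0.29 (-0.50 to -0.08) and 0.05 (0.04 to 0.06), and the values of macrophage and mast cell markers there were 0.03 by CPM for both. The sum of the scar matrix list, by which these regions are defined, lay at 0.23 (0.21 to 0.25) in the matrix-rich regions and at -0.051 (-0.066 to -0.037) in the others, although it was 0.27 by CPM there. The sum of endocardial markers lay at -1.20 (-1.36 to -1.05) and at 0.030 (-0.12 to 0.18), and 0.35 by CPM in the others. Taken apart, which was chosen after the values were seen, region 4 and region 6 differed. In region 4, MHC class II genes lay at 1.49 (1.13 to 1.87), stress genes at 1.72 (1.66 to 1.78), macrophage markers at 0.13 (0.01 to 0.25) and mast cell markers at -2.74 (-2.96 to -2.53). In region 6 the same lists lay at -1.66 (-2.48 to -0.89), with 53 and 20 class II UMIs, 0.41 (0.31 to 0.50), -0.55 (-0.74 to -0.35) and 0.57 (-0.47 to 1.67), and red blood cell genes lay at -2.05 and -1.75 in region 4 and region 6.

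The genes with the highest ratios included secreted immune factors and stress genes. Sprr1a, a small proline-rich protein of stressed cardiomyocytes and epithelia, lay at 4.0 (2.62 to 5.90), with 4 and 148 UMIs. Ccl5 lay at 3.40 (2.49 to 4.47), Retnla, a secreted product of alternatively activated macrophages, at 3.21 (2.30 to 4.29), and Mmp12, the macrophage elastase, at 3.03 (2.20 to 4.01), with 75 of its 227 PD1 KO UMIs in 1 spot. Without the spot with the most UMIs in each section, the CPM ratio of Ccl5 was 5.99-fold in place of 13.2-fold. Il2, the T cell growth factor gene, had 10 and 174 UMIs and lay at 2.91 (2.0 to 4.0), spread over 160 PD1 KO spots with at most 2 in each, and 42.4% of the 31-mers of its annotated 3' end also occur in Ntan1. Pdk4, Nppa and Fos, described with their lists, were among the 15. Mns1, Rbm8a2 and Aldoart1 lay at 2.18, 2.49 and 2.84, with 0%, 7.30% and 0% of their 3' ends shared, and Amd2, Eno1b, Nutf2-ps1 and Tpm3-rs7, between 1.85 and 2.24, have 3' ends shared with Amd1, Eno1, Nutf2 and Tpm3.

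Of the genes with the lowest ratios, Ccl21a, a chemokine of lymphatic vessels that guides T cells and dendritic cells, lay at -3.76 (-4.28 to -3.26), with 228 UMIs in 39 PD1 Het spots and 39 UMIs in 15 PD1 KO spots, and its 3' end is shared with 2 other genes. Cntn2 lay at -2.21 (-2.77 to -1.66) and Pcp4, which encodes a calmodulin regulator, at -2.01 (-2.45 to -1.57). Gstp1 lay at -1.92 (-2.21 to -1.64), Hmga1, whose 3' end is shared with Hmga1b, at -1.71 (-2.21 to -1.23), and Polr2l at -1.42 (-1.54 to -1.30). Saa3, an acute phase protein, lay at -1.52 (-2.07 to -0.98), with 33 of its 66 PD1 Het and 43 of its 53 PD1 KO UMIs in 1 spot of each section, and without these spots its CPM ratio was 0.165-fold in place of 0.438-fold. Nrp1, Ms4a4d, Ankmy1, Stard10, Smoc1 and Osr1 lay between -1.41 and -1.31, and Tpsb2 and Lyve1 completed the 15. Pcp4, Cntn2, Stard10 and Smoc1 are among the leading genes of region 6. Ccl21a and Lyve1 are among those of region 7, which held 19 PD1 Het and 16 PD1 KO spots. The ratios of these genes can depend on how much of such small areas a section holds, which was not tested. At a minimum of 300 UMIs, 4 of the 15 highest and 4 of the 15 lowest genes remained among the named genes.

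**Figure D3:**
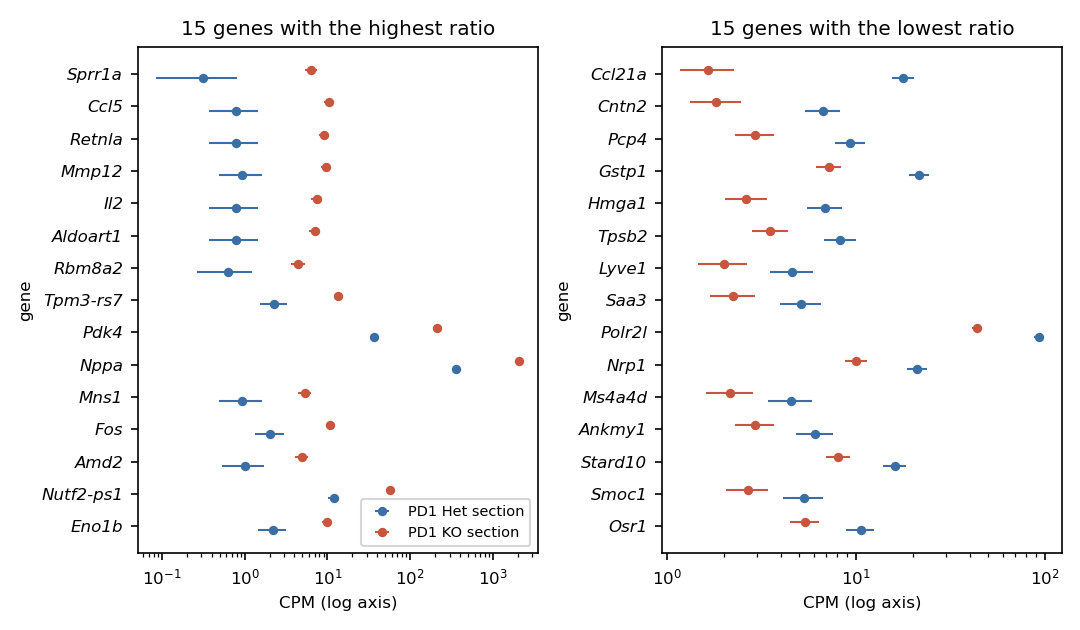
CPM of the 15 genes with the highest and the 15 with the lowest ratio in the PD1 Het section (blue) and the PD1 KO section (red), on log axes, with exact Poisson 95% intervals. The ratios run from Sprr1a, with 0.312 and 6.29 CPM, to Ccl21a, with 17.8 and 1.66 CPM.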

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

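The sex-linked genes were listed before the data were examined, and no test was run on them. The sections differ in the sex of the animals as well as in genotype. In the PD1 KO section the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 2900 UMIs together, or 123 CPM, against 1 UMI in the PD1 Het section. Xist had 541 UMIs, or 42.2 CPM, in the PD1 Het section and 1 in the PD1 KO section. These genes lie outside the comparison of the genotypes, and their counts are above the limit that a count of 0 allows. With 1 animal per group, a difference between the sections cannot be assigned to genotype rather than to sex.

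A search for lists on opposite sides in the fifth of spots with the most matrix and in the other spots was set up after the values were seen. It asked for intervals on opposite sides of 0 both by CPM and relative to the median gene, and 0 lists met this. By CPM alone 5 lists did, namely ventricular cardiomyocyte markers, glycolysis genes, endothelial markers, endocardial markers and red blood cell genes. Relative to the median gene alone 2 lists did, namely macrophage markers and complement genes. Between the parts of the sections the difference itself was not tested.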

How the results depend on the processing

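The TMM scaling of Cd274, the ratios without the spot with the most UMIs, the stress list without Nppa and the matrix-rich regions taken apart were chosen after the data were seen, and all other alternatives before the data were examined. No paired analysis was possible because each group has 1 section, and for the same reason no replicate could be left out. All log2 ratios in this part are CPM ratios unless called relative to the median gene. A value is called turned where its CPM interval excluded 0 and the new value lay beyond 0 by more than 50% of the width of that interval; smaller changes of sign are given apart. With no spot filter, with at least 2000 UMIs per spot, and with list members of at least 1 or at least 50 UMIs, no result turned or left its interval, though the neutrophil median changed sign with members of at least 1 UMI (-0.49). The 3 other scalings add 1 constant to every log2 CPM ratio (-0.31 for TMM and for median-of-ratios, -0.20 for the reduced total), so by construction each list moves by that amount and lists near 0 turn sign.

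With edgeR TMM factors the median turned for ventricular cardiomyocyte markers (-0.22), glycolysis genes (-0.25), fibroblast markers (-0.19) and endothelial markers (-0.14). The summed ratio turned for ventricular cardiomyocyte (-0.30), atrial (-0.13), fibroblast (-0.17), endothelial (-0.15) and smooth muscle (-0.18) markers, and for fatty acid oxidation (-0.061), monocyte and injury macrophage (-0.083) and type I interferon response genes (-0.21). Medians that kept their direction moved to 0.32 for fetal and stress cardiomyocyte genes, 0.44 for scar matrix, 0.12 for macrophage markers, -0.81 for resident and reparative macrophage genes, 1.06 for MHC class II, 0.35 for MHC class I and 0.49 for cell cycle genes. With median-of-ratios size factors the turned medians were -0.22, -0.25, -0.19 and -0.14 for the same lists, and the turned sums -0.30, -0.13, -0.17, -0.15, -0.19, -0.063, -0.085 and -0.21. The moved medians were 0.32, 0.44, 0.12, -0.81, 1.05, 0.35 and 0.49. Under each of these scalings 15 further values changed sign, namely the medians of atrial, fatty acid oxidation, smooth muscle, pericyte, epicardial, neutrophil, type I interferon, hypoxia, red blood cell and Schwann cell genes, and the sums of endocardial, resident macrophage, T cell, complement and Schwann cell genes.

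With the reduced total, the median turned for ventricular cardiomyocyte markers (-0.12), glycolysis genes (-0.14) and fibroblast markers (-0.083). Sums turned for ventricular cardiomyocyte (-0.19), fibroblast (-0.064), endothelial (-0.046) and smooth muscle (-0.081) markers and type I interferon response genes (-0.10). Moved medians were 0.42 for fetal and stress cardiomyocyte genes, 0.55 for scar matrix, 0.22 for macrophage markers, -0.70 for resident and reparative macrophage genes, 0.45 for MHC class I and 0.60 for cell cycle genes. A further 10 values changed sign, namely the medians of endothelial, neutrophil, type I interferon, red blood cell and Schwann cell genes, and the sums of atrial, endocardial, resident macrophage, T cell and Schwann cell genes. With the mean of spot CPM, the neutrophil median changed sign to -0.37, the ventricular cardiomyocyte median moved to 0.073, its sum turned to -0.012 and the red blood cell sum to 0.046.

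Without matrix-rich regions, the medians were 0.13 for ventricular cardiomyocyte markers, 0.42 for fetal and stress cardiomyocyte genes, 0.33 for scar matrix, 0.074 for macrophage markers and 0.80 for MHC class II by CPM, or -0.20, 0.094, 0.0043, -0.25 and 0.47 relative to the median gene of those spots, and the red blood cell sum turned to 0.37. A further 8 values changed sign there, namely the medians of atrial, glycolysis, endocardial (0.56), neutrophil and cytotoxic (-0.15) genes and the sums of atrial, mast cell (0.030) and Schwann cell genes. In matrix-rich regions only, the medians moved to 0.045 for ventricular cardiomyocyte markers, 1.35 for fetal and stress cardiomyocyte genes, -0.72 for resident and reparative macrophage genes, 1.85 for MHC class II and 0.66 for cell cycle genes by CPM, or -0.13, 1.17, -0.90, 1.67 and 0.48 relative to the median gene of those spots. There the median turned for fibroblast (-0.25) and endothelial (-0.17) markers, and the sum for atrial (-0.23), fibroblast (-0.28), endothelial (-0.13), smooth muscle (-0.11), monocyte and injury macrophage (-0.17) and type I interferon response (-0.094) genes. A further 10 values changed sign, namely the medians of atrial, smooth muscle, neutrophil, type I interferon and red blood cell (-1.76) genes and the sums of glycolysis (0.11), endocardial (-1.02), resident macrophage (-0.30), B cell (0.045) and adipocyte (0.14) genes. In region 6 alone the summed ratio of the matrix-rich regions turned for MHC class II genes (-1.53), macrophage markers (-0.42), mast cell markers (0.70) and resident and reparative macrophage genes (0.18), and in region 4 alone none turned. Without Nppa the median of fetal and stress cardiomyocyte genes moved to 0.52 by CPM, or 0.19 relative to the median gene. For the spot mean and the regions, the cause was not tested.

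At other rankings and clusterings no result turned, but many left their interval. With 10 bins 9 results left it and 3 stayed, and with the fibroblast ranking 7 left it and 5 stayed. At resolution 0.3 and with centred genes 4 left it and 6 stayed. At resolution 1 these counts were 5 and 5, and with immune genes 3 and 7. Cell cycle genes in the PD1 Het section changed sign with 10 bins (-0.031) and with the fibroblast ranking (-0.011), as did macrophage markers in the other regions at resolution 1 (-0.0087). Without thinning, the order of the sections turned for B cell markers, with 26.5% of PD1 Het spots and 33.0% of PD1 KO spots, since the PD1 KO spots are deeper. At 5000 UMIs per spot the B cell shares were 9.81% and 9.67%, and the neutrophil shares 5.66% and 3.66%. Lists with few UMIs have wide intervals, and a count of 0 allows 0.234 CPM in the PD1 Het section and 0.128 CPM in the PD1 KO section.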

Other observations

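All tests in this part were chosen after the results were seen, and so were the genes outside the rule for named genes. Nnt, the mitochondrial transhydrogenase, which carries a deletion in the C57BL/6J substrain, had 62 UMIs (4.84 CPM) in the PD1 Het section and 494 UMIs (21.0 CPM) in the PD1 KO section, a relative log2 ratio of 1.79 (1.40 to 2.19). The labels give the strain as C57BL/6 with no substrain. Around Pdcd1, 3 of 46 genes within 5 Mb (6.52%, 1.37 to 17.9) lay at least 1.5-fold from the median gene, against 8.81% of 11409 other genes. Windows of 2, 10 and 20 Mb were also looked at and gave 4.35%, 8.96% and 7.2%. Ankmy1, among the 15 lowest ratios, starts 1.18 Mb from Pdcd1.

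Red blood cell genes were arranged differently in the sections. In the spots with the most matrix, the highest of the 5 bins, they were 1.37-fold (1.35 to 1.39) the level of the other spots in the PD1 Het section and 0.588-fold (0.579 to 0.597) in the PD1 KO section. Atrial markers were 4.11-fold (3.56 to 4.74) and 4.26-fold (3.86 to 4.70), and complement genes 4.79-fold (4.41 to 5.20) and 3.65-fold (3.45 to 3.86).

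MHC class II genes were higher in the PD1 KO section. At matched matrix share the summed list was 1.87-fold higher, against 1.19-fold for the median gene. This argues against a larger matrix share alone as the whole cause. The bin with the most matrix had no upper limit, with shares up to 7.59% in PD1 Het and 11.6% in PD1 KO spots. Spots were not matched on the kind of matrix-rich tissue, and class II genes lay at 1.49 in region 4 and -1.66 in region 6. A larger amount of 1 kind of matrix-rich tissue therefore stays open. More macrophages of the same kind are argued against as the whole cause by the fold of the summed class II list over that of the macrophage markers, 2.03 (1.84 to 2.25). A different kind of macrophage or other cells with class II genes may still account for the higher level. Sequence differences from the reference at the MHC locus of chromosome 17 are argued against for Cd74, which lies on another chromosome and was 2.57-fold (2.21 to 3.01) higher against 1.26-fold for the median gene, and as the whole cause for the members on chromosome 17, since their fold in the fifth of spots with the most matrix was 2.20 (1.66 to 2.96) times that in the other spots. Genotype, the sex of the animals and the section itself stay open and untested, because each differs between the same 2 libraries, and a difference in strain background was not tested.

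Immediate early and heat shock genes were 1.75-fold (1.67 to 1.84) higher at matched matrix share against 1.19-fold for the median gene, which argues against more matrix-rich tissue as the whole cause. A candidate explanation is a difference in handling before freezing, which would act on all parts of a heart, and the fold in matrix-rich spots over that in other spots was 0.988 (0.887 to 1.1). Genotype and sex could give the same even spread, so this value does not separate them.

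Among the copy-like genes with large ratios, reads shared with near-identical copies may account for part, since of the 151 genes with a shared 3' end, 15.2% (9.91 to 22.0) lay 2-fold or more from the median gene, against 1.60% of genes without one in the same count range. For Cd274 this is argued against, as 0% of the 31-mers of its 3' end occur in another gene and no other gene holds more than 1.57% of those of its transcripts. The gene that holds this 1.57% is the Y-linked Uty, with 0 UMIs in the PD1 Het section and 331 in the PD1 KO section. Whether any Cd274 UMIs came from that stretch was not tested. For Il2 the explanation by shared reads stays open, as 42.4% of the 31-mers of its 3' end occur in Ntan1, which had 469 and 589 UMIs. For Aldoart1 and Rbm8a2, whose 3' ends share 0% and 7.30%, it stays open too, since 10.2% and 26.3% of the 31-mers of their transcripts occur in Aldoa and Rbm8a. Whether sex, strain or genotype sets these ratios was not tested.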
